A study of Homo sapiens with 2 samples.

How the data were processed

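RNA of the SW620 LiM2 cell line was measured on a human Affymetrix HG1.0ST gene expression array, 1 array of untreated cells and 1 array of cells treated with the MEK1/2 inhibitor U0126 at 10 µM for 24 h. Per the labels' protocols, total RNA was extracted with a column kit and labelled with biotin. The deposited log2 values were made by the authors with RMA in the oligo package, per the submitters' processing notes, which name no versions. RMA corrects the background, brings the arrays to a common distribution of probe signals and summarises the probes of each probe set on a log2 scale by median polish. Per the series design text, 9 arrays were processed together. The other 7, of the parental line and of further untreated LiM2 cultures, are not analysed here. Because RMA draws on every array in a batch, the values of the 2 arrays used here depend in part on the 7 not analysed.

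The table held 33297 probe sets and 2 columns of log2 values, 1 per array, with no column left over. Their range, 3.00 to 14.0, is that of log2 signals from a scanner, and rows had not been centred. The direction of each difference follows from the labels of the columns. Exactly equal values on both arrays were found in 464 rows. Both values were shared with at least 1 other row in 1028 rows, which held 442 distinct pairs of values.

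The table gives probe set IDs only, and no table pairing them with genes was used here, so every result is for probe sets and none for a named gene. A total of 37 gene lists had been fixed before the data were examined, among them ERK target genes, cell cycle genes and markers of other cell types. None of the lists was measured, and no random lists were drawn. The comparisons planned for ANGPT2 and CXCR4, the averaging of probe sets by gene, and the exclusion of uncharacterised genes, microRNAs and small RNAs from the naming rule were also left out. The naming rule took the 10 largest differences in each direction. Since the IDs carry no gene, 2 per direction are printed and the others are summarised. Control probe sets on the array were not told apart from the others and were kept.

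The difference of a probe set is its log2 value on the treated array minus that on the untreated array. With 1 array per group there is no replicate, so no spread between cultures or arrays was estimated and no test was made. The number of arrays limits the precision of every value. Probe sets were counted as past the size threshold when the difference was 1 or more in either direction, which is a 2-fold difference, among probe sets whose mean over both arrays was at or above the median of all row means, 8.12. The rule had been planned for genes with 1 symbol, filtered at the median gene mean. Probe sets took their place because no gene symbols were used here. The size threshold and a filter at the median were themselves set before the data were examined. Alternatives set then were no filter on level, filters at the 25th and 75th percentiles of row means, size thresholds of 1.5-fold and of 1.5 on the log2 scale, quantile normalization of the 2 columns, subtraction of the median difference, and subtraction of a loess curve of the difference on the mean level (span 0.2, 3 robustness iterations). Leaving out a run of consecutive IDs, keeping 1 row per pair of identical values, and filtering on the higher of both values were added after seeing the data.

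The counting was tested on simulated data, with 2 arrays built from the real levels of all 33297 probe sets, normal noise of SD 0.15 and 200 changed probe sets. At a size of 2 on the log2 scale, 100% of the raised and 76% of the lowered probe sets were recovered, with 0 false calls. At a size of 1.3, 88% of the raised and 80% of the lowered probe sets were recovered. Without the filter on level, 100% of both were recovered at a size of 2, and 88% of the raised and 92% of the lowered at a size of 1.3. All changed probe sets were drawn from those above the filter, so lowered ones near its edge were removed by it. The noise SD of 0.15 on each array was chosen, not estimated from the data. The real differences between the 2 arrays had an SD of 0.40 across probe sets. That SD takes in the noise of both arrays and any real changes, so it is not a like measure. The 0 false calls therefore hold for the chosen noise only and do not measure false calls in the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.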

Results

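SW620 is an established human line from a metastasis of a colon adenocarcinoma, and LiM2 is the name the labels give to the derivative studied here. U0126 blocks MEK1 and MEK2, the kinases that phosphorylate and activate ERK1 and ERK2. The series title names ANGPT2, an angiopoietin that acts on blood vessels, and CXCR4, a chemokine receptor, as genes under ERK1/2 control. The comparison asks which transcripts differ in LiM2 cells after the inhibitor. It rests on 2 arrays, 1 of untreated cells and 1 of cells kept in 10 µM U0126 for 24 h, each with 33297 probe sets. Probe sets are reported by ID, and no value is given for a named gene. The log2 signals had a median of 8.14 and quartiles of 6.65 and 9.94 on the untreated array. On the treated array the median was 8.09, with quartiles of 6.61 and 9.83.

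Most probe sets differed little between the arrays, and those that differed strongly were mostly lower on the treated array. The difference was under 0.5 on the log2 scale for 28548 probe sets, or 85.7% of them, and the median difference, treated minus untreated, was -0.04. Among the 16649 probe sets at or above the median level, 476 were lower in the treated array by 1 or more on the log2 scale, a 2-fold difference, and 142 were higher. The lower probe sets were thus 77.0% of the 618 past this size. After quantile normalization of the 2 columns they were 66.6%, with 397 lower and 199 higher. With an opening run of consecutive IDs left out, a choice made after seeing the data, 408 were lower and 133 higher. That run may hold control probe sets of the array, which the sources used here do not say. These counts compare single arrays: no test was made, and how many probe sets would differ by as much between untreated cultures is not measured by the arrays used here.

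**Figure D1:**
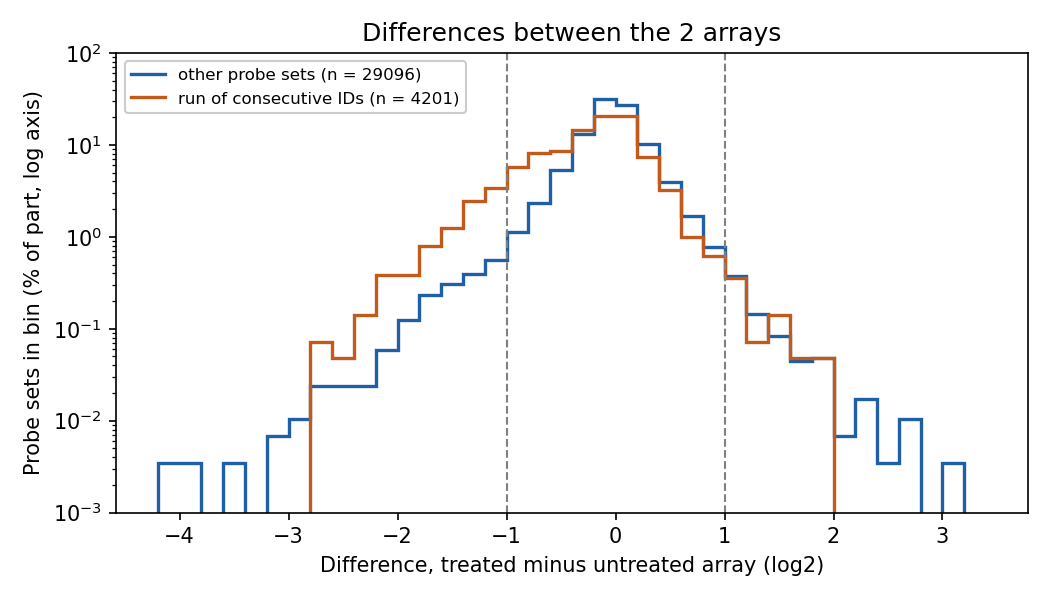
Share of probe sets (percent of each part, log axis) by difference between the treated and the untreated array (log2, bins of 0.2), for the 4201 probe sets in the opening run of consecutive IDs and the other 29096. Dashed lines mark differences of 1 in either direction, beyond which 376 probe sets of the run were lower and 28 higher, against 518 lower and 214 higher among the others.

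The largest differences on the low side exceeded those on the high side. Probe set 7965335 had a signal of 11.09 on the untreated array and 7.00 on the treated array, a difference of -4.09 on the log2 scale, so that its signal in untreated cells was 17.1-fold that after the inhibitor. Probe set 8015806 followed with signals of 11.46 and 7.64, a difference of -3.81 and a 14.1-fold higher signal in untreated cells. Among probe sets at or above the median level, the 10 largest negative differences ranged from -4.09 to -2.67. Over all rows, 5 probe sets were lower by 3 or more, of which 4 were at or above that level.

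On the high side, probe set 7990391 had a signal of 7.23 on the untreated array and 10.42 on the treated array, a difference of 3.19 and a 9.13-fold higher signal after the inhibitor. Probe set 7940622 had signals of 7.47 and 10.13, a difference of 2.66 and a 6.32-fold higher signal. Among probe sets at or above the median level, the 10 largest positive differences ranged from 1.97 to 3.19. Over all rows, 12 probe sets were higher by 2 or more. At a difference of 2 or more, 41 probe sets at or above the median level were lower and 9 were higher, and at 3 or more 4 were lower and 1 was higher.

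Differences of 1 or more were spread unevenly over the range of mean signal. In 10 bins of mean level of 3329 or 3330 probe sets each, the bin from 9.50 to 10.29 held the most lower probe sets, 143, together with 40 higher ones. The bin from 10.30 to 11.30 held 97 lower and 18 higher probe sets. The brightest bin, from 11.30 up, held 18 lower and 3 higher. Of its 3330 probe sets, 1030 belonged to the opening run of consecutive IDs, with 0 lower and 1 higher. The other 2300 held 18 lower and 2 higher. Over all rows, lower probe sets outnumbered higher ones in all 10 bins, but in the dim bins this rested largely on the opening run of consecutive IDs. In the bin from 5.14 to 6.27, 105 of the 123 lower probe sets belonged to that run. Outside the run, the 5 bins up to the median level held, from the dimmest up, 4 lower and 4 higher probe sets, 18 and 12, 15 and 14, 24 and 22, and 49 and 29. Whether the run holds control probe sets of the array is not given in the sources used here, and 68 of the 476 lower and 9 of the 142 higher probe sets came from it. With the run left out, a choice made after seeing the data, the counts at or above the median level were 408 lower and 133 higher.

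**Figure D2:**
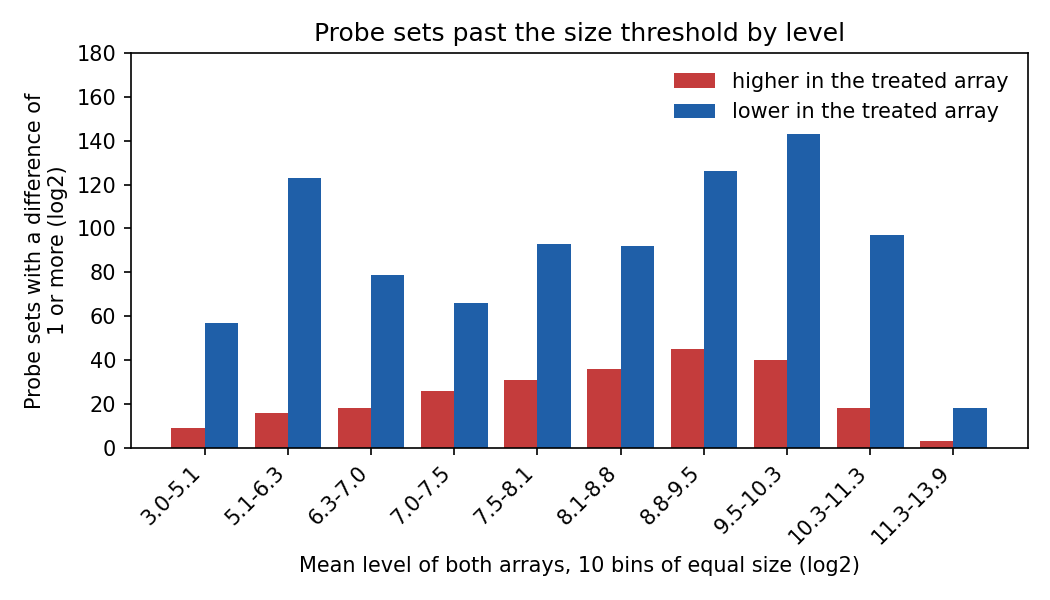
Number of probe sets (y axis) with a difference of 1 or more on the log2 scale, higher or lower in the treated array, in 10 bins of equal size of the mean log2 level of both arrays (x axis, the range of each bin). Lower probe sets outnumber higher ones in each bin over all rows, but outside the opening run of consecutive IDs, which is not drawn apart, the dimmest bin holds 4 of each. Both are few in the brightest bin, with 18 lower and 3 higher.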

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

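Lower probe sets outnumbered higher ones under all 11 alternatives run, with shares of lower ones from 66.6% to 83.3%. The lowest share came from quantile normalization of the 2 columns and was the only one over 10 percentage points from the reported 77.0%. Counts followed the filter and the size threshold. Without a filter 242 probe sets were higher and 894 lower, at the 75th percentile of level 41 and 189, at a threshold of 1.5-fold 637 and 1443, and at 1.5 on the log2 scale 34 and 170, each by construction of a looser or stricter rule. The other 7 alternatives gave counts within 1.5 times the reported ones. The 4 probe sets printed by ID moved by 0.1 or less under each of the 3 other normalizations. Alternatives planned for gene lists, ANGPT2, CXCR4 and the averaging of probe sets by gene were not run, as probe sets were not paired with genes here. No replicate could be left out with 1 array per group, and the signal over background of each probe set is not given in the values used.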

Other observations

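The tests on the opening run of consecutive IDs, the share without that run and the weighing of single arrays were chosen after the result was seen.

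Probe sets with successive IDs had weakly similar differences. Outside the opening run of consecutive IDs, Spearman's rho between the differences of successive probe sets was 0.0985 across 29096 probe sets, which are not independent replicates, while the highest of 1000 shuffled orders gave 0.0159. At distances of 2, 5, 10 and 50 places it was 0.0411, 0.0163, 0.0094 and 0.0132, across 28514 probe sets with 1 row per pair of identical values. No shuffles were run at these distances. The highest of 1000 shuffled orders of these rows gave 0.0175 for successive probe sets, above the values at 5, 10 and 50 places. Rows with identical values do not account for the likeness of successive probe sets, since rho was 0.0912 without the repeats. Neither does a trend of the difference with level, since rho was 0.0920 after a loess curve was subtracted. Neighbouring pairs with differences of 1 or more were counted over all levels outside the run, with 1 row per pair of identical values. Those in the same direction numbered 53, against a mean of 10.8 and a maximum of 22 in shuffled orders. Those in opposite directions numbered 8, against a mean of 7.57. Counted on the same rows, also over all levels, there were 7 stretches of 3 or more successive probe sets with differences of 1 or more in one direction. Of these, 6 were lower in the treated array, and the longest held 8 probe sets with a median difference of -1.48. Probe sets that share part of their probes, or that lie near each other in the genome, may explain the likeness, and both stay open without the array's annotation.

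The excess of lower over higher probe sets was weighed against the processing. It was not removed by subtracting the median difference, after which 72.7% of the probe sets past the size threshold were lower, nor by subtracting a loess curve on level, after which 69.9% were. Quantile normalization of the 2 columns cut the share most, to 66.6%. The median difference was -0.04, and -0.095 in the bin from 10.30 to 11.30, both small beside the threshold of 1. These subtractions therefore test only shifts of the size seen and cannot set aside other effects of the processing. Without the opening run of consecutive IDs 75.4% were lower. Outside the run the excess depended on level, with 70.8% lower over all rows, but 4 lower and 4 higher in the dimmest of 10 bins and 24 and 22 in the bin from 6.95 to 7.54. With 1 array per group, an effect of the inhibitor cannot be told apart from a difference between single cultures, labelling reactions or hybridisations, and no biological explanation was tested.

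The first 4201 probe sets by ID form a nearly unbroken run of consecutive numbers, with a median gap of 1 against 7 among the other 29096, and what they target is not given in the sources used here. They were lower in the treated array more often than the others: 376 of them, or 8.95%, were lower by 1 or more on the log2 scale and 28 higher, against 1.78% lower among the others. A trend with level, or a lower background that acts alike on all probe sets of like level, is argued against. The run's median lay more than 0.1 below that of other probe sets of like level in 7 of the 10 level bins. Probe sets of like level may differ in how much of their signal is background, so this comparison cannot decide on a lower background in general. In the bin from 6.27 to 6.95 the run's median difference was -0.55 and that of the others 0.00, while in the brightest bin the run's was 0.01. The run's spread was larger than that of the others in the 6 dimmer bins, with an SD of 0.66 against 0.29 in the bin from 5.14 to 6.27, and smaller in the 4 brighter ones, with 0.20 against 0.28 in the brightest. Noise alike in both directions would not make 93.1% of the run's 404 probe sets with a difference of 1 or more, counted over all levels, lower or move its median, so it is argued against as the whole account, while its part in the size of the counts stays open. The run may hold control probe sets of the array, in which case its calls are not transcripts of interest, and this stays open. A class of target that makes up the dim part of the run, and that the inhibitor or the handling of 1 RNA sample affects, stays open and untested.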
